A study of Mus musculus with 6 samples.

How the data were processed

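RNA-seq was analysed from 6 mouse medulloblastoma samples, 3 labelled wild type and 3 labelled Eed mutant. Total RNA was extracted with TRIzol, cleaned on columns and made into Illumina RNA-seq libraries, per the labels' protocols. Strand, read length and the method of RNA selection were not given in the sources used here. The deposited files hold kallisto estimated counts and TPM (a length-scaled measure of transcript abundance) per transcript, per the file headers, with 1 file per sample and no pooling of replicates. The submitters' processing notes name kallisto 0.43.1 and the mouse builds GRCm38 and mm10, which are the same assembly. The 131100 transcripts of each file carry GENCODE identifiers and gene symbols. The GENCODE release was not given in the sources used here.

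Each deposited file also carries a code in its name, whose meaning (an age or a batch, for example) was not given in the sources used here. A code is shared by wild-type replicate 2 and mutant replicates 1 and 2, another is shared by wild-type replicate 3 and mutant replicate 3, and wild-type replicate 1 has a code of its own. The codes were not used to group samples. With at most 3 libraries per code no test within a code was made, and the code was instead added as a term to the fits, in which wild-type replicate 1 then adds nothing to the comparison of the groups.

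Estimated counts were summed over the transcripts of each gene and rounded to whole numbers, which gave 52550 genes. GENCODE M21 on GRCm38 supplied coordinates and gene types, and 52403 genes matched it by identifier while 147 did not. Symbols were kept as the files give them, although 4327 differ in M21. The libraries held 26330605, 26310140 and 26186236 estimated counts in wild-type replicates 1 to 3 and 26299365, 26399821 and 26425111 in mutant replicates 1 to 3. At that depth 3 counts correspond to 0.114 CPM, the library-scaled count, per library, which was the floor used for genes with no counts in a group. Intervals and floors cover counting error only. Reads shared between near-identical or overlapping genes were divided by the estimation step, so H2-Q4, H2-Q7, the Pcdha genes and Hspa1b are uncertain. A gene and its antisense partner cannot be separated without strand.

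The groups were compared with edgeR 4.0.16 (TMM normalization, default expression filter, quasi-likelihood F-test) in R 4.3.3, which tested 19145 genes with Benjamini-Hochberg adjustment at 0.05. Levels are CPM scaled by TMM factors, given as mean ± SD over 3 samples, and log2 fold changes are mutant minus wild type. The test, the sample groups, the alternatives, the rule for named genes and 34 gene lists were chosen before the data were examined. The lists were drawn from textbook knowledge and cover chromatin complexes, developmental regulators, signalling pathways, cerebellar lineages, handling signs and other cell types that a tumour piece could hold. Of the list genes, 1 (Ahsp) had no match in the files. Lists with at least 5 tested members, 33 in all, were tested with camera in limma 3.58.1 on log CPM (prior count 2, preset correlation 0.01), adjusted over the lists. Members were counted from the edgeR fit adjusted over all genes and adjusted over the list alone. Camera with an estimated correlation and fry, a rotation test, were run beside it.

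Named genes were 20 fixed ones plus, for each list with a called member, up to 4 called members with non-overlapping groups and a mean of at least 1 CPM. The 10 largest rises and the 10 largest falls among called protein-coding genes under the same conditions completed the rule. Under edgeR the last parts of this rule gave 0 genes, where 3459 genes had an unadjusted p under 0.05 and DESeq2 called 923. The rule was therefore applied to calls of DESeq2 1.42.0, already listed as another test, and this use was chosen after seeing the data. Other list members named in the text passed the edgeR test adjusted over the list alone or illustrate a list, and were likewise chosen after their values were seen. Some genes that the rule names are not reported here.

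The alternatives listed beforehand were RLE size factors, library size alone, DESeq2, limma-voom on unrounded counts, limma-trend on log2(TPM + 1), an effective length offset and no filter on low counts. A stricter filter (CPM of at least 1 in at least 3 samples), a minimum absolute log2 fold change of 1, an adjusted p below 0.01, protein-coding genes only, the replicate number as a block and leaving out each library were also listed. Robust and bias-adjusted edgeR fits, sex as a covariate, the file code as a term, and the alternatives to the DESeq2 counts and to the counts within lists were added after seeing the data. All 10 splits of the 6 samples into 3 and 3 were refitted.

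The fits were tested on simulated counts for the 19145 genes, with 5 draws of 200 changed genes, 100 at each of 2-fold and 4-fold. edgeR recovered 64.2% of the 2-fold and 95.4% of the 4-fold changes, and 7.32% of its calls were false. DESeq2 recovered 75.8% and 96%, and 22.96% of its calls were false. Changed genes had a mean of at least 20 counts, and the dispersions came from the edgeR fit. These shares therefore need not hold for the data, where edgeR called 0 genes. Camera called a known set of 20 genes in 5 of 5 draws and 0 of 33 unchanged lists, with the preset and with the estimated correlation. The simulated genes were drawn independently of each other, so this could not show false calls that come from correlated list members. In the data the estimated correlation ran from -0.134 for cyclin-dependent kinase inhibitors to 0.738 for proliferation genes. No 2 libraries of the same group matched within sampling noise, so all 6 were counted. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures.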

Results

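Medulloblastoma is a malignant tumour of the cerebellum. Eed is a core subunit of Polycomb repressive complex 2 (PRC2), which places a repressive methyl mark on histones at many developmental genes. Gene expression was measured by RNA-seq in 3 wild-type and 3 Eed mutant mouse medulloblastomas to ask which genes differ with the Eed genotype. Nothing in the labels says that the tumours came from separate animals, so p-values measure only the spread between these samples. Depth was nearly equal, from 26186236 to 26425111 estimated counts per library, with 28424 to 28635 genes above 0 and 4.94% to 5.47% of counts from mitochondrial genes. The first principal component held 35.1% of the variance and separated the groups, at -26.1, -49.2 and -9.36 in wild-type replicates 1 to 3 and 38.4, 18.5 and 27.8 in mutant replicates 1 to 3. Wild-type replicate 2 lay at the end of this component. Both groups held both sexes by expression: Xist was at 1859 to 1988 CPM in wild-type replicate 3 and mutant replicates 1 and 2, and at 0.64 to 1.32 CPM in the remaining 3 libraries, which expressed Y-linked genes.

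Eed RNA was present in all 6 tumours and differed by less than the spread between them. The gene (ENSMUSG00000030619.9, chromosome 7, 89954654 to 89980983, minus strand) measured 43.8, 30.1 and 35.6 CPM in wild-type replicates 1 to 3 and 32.6, 36.8 and 30.7 CPM in mutant replicates 1 to 3. The means were 36.5 ± 6.87 and 33.3 ± 3.12 CPM (SD, n = 3), and the log2 fold change was -0.13 (SE 0.144, adjusted p = 0.656 in edgeR). Its sign reversed without wild-type replicate 1 (0.02), with the file code as a term (0.02) and on the TPM (0.01) and length offset (0.05) scales. The mutant allele was not given in the sources used here, so this level does not check the labels. A pair of short transcripts at the start of the gene, Eed-202 with 2 exons and Eed-203 with 3, are annotated as retained introns, and the last exon of each runs on into the intron that follows it in Eed-201. Their counts can therefore hold intron signal. They took 3.17%, 6.87% and 1.30% of Eed counts in wild type and 10.5%, 13.4% and 7.77% in the mutants. The means were 3.78% ± 2.84 and 10.6% ± 2.83 (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). The pair was picked from all Eed transcripts, and its test was not among those set beforehand. Eed-208, also annotated as a retained intron, went the other way. It had 51.7, 61.9 and 64.6 counts in wild type and 41.3, 35.3 and 41.2 in the mutants. Eed-202 had 0 estimated counts in each wild-type library and 4.73, 7.93 and 3.53 in the mutants. Of all transcripts, 76 of 97426 transcripts with counts had 0 in wild type and at least 3 in each mutant, 71 had the reverse, and another split of the samples gave 81. The full-length 12-exon transcript, Eed-201, had 798, 478 and 629 counts in wild type and 518, 575 and 503 in the mutants.

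**Figure D1:**
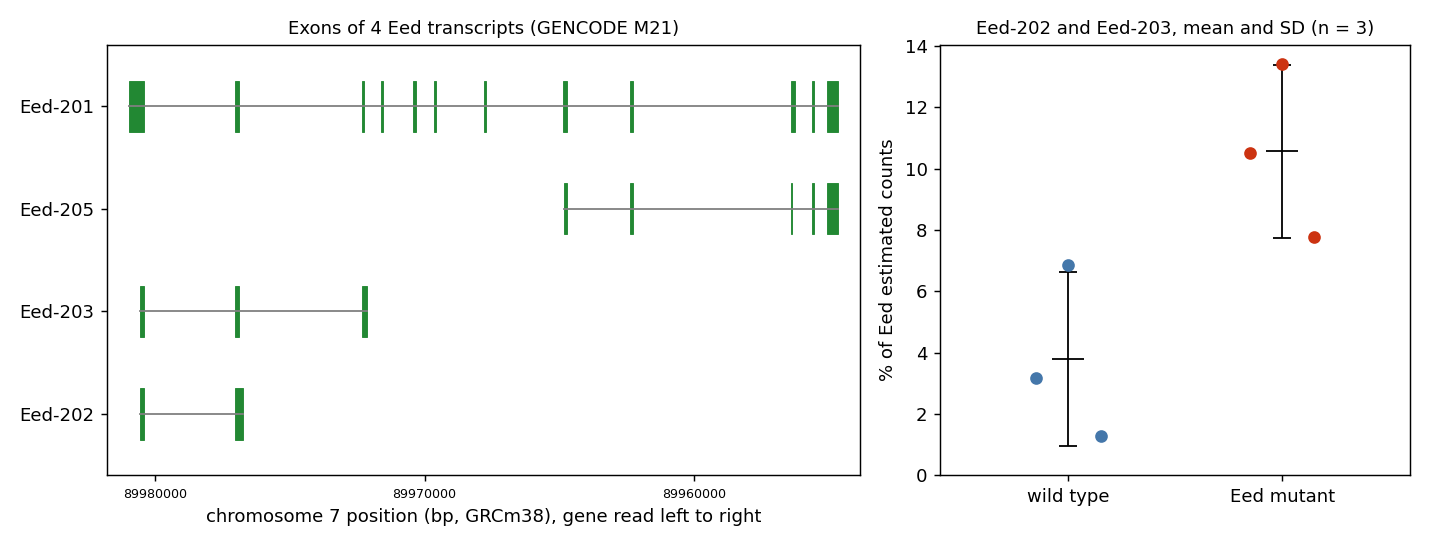
Left, exons (boxes) of 4 Eed transcripts in GENCODE M21 along chromosome 7 (position in bp, GRCm38), drawn in the direction of transcription. Right, the share of Eed estimated counts (%) from Eed-202 and Eed-203 per library (points) with mean and SD (n = 3), which lay at 1.30% to 6.87% in wild type and 7.77% to 13.4% in the mutants.

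The Eed mutant tumours had higher levels of skeletal and cardiac muscle genes, Hox genes, other developmental transcription factors and imprinted genes, among them Igf2 and H19. Notch and Hedgehog pathway genes were also higher. Markers of oligodendrocytes and Purkinje cells were lower. Those of differentiated granule neurons were lower as a list, but their median log2 fold change went from -0.39 to -0.16 without wild-type replicate 2. edgeR's quasi-likelihood test called 0 of 19145 genes higher and 0 lower at an adjusted p of 0.05, with 0.0808 the smallest value. At an unadjusted p under 0.05 there were 3459 genes, 1779 higher and 1680 lower, against 957 expected with no effect. DESeq2 called 524 genes higher and 399 lower of 17679, limma-voom called 1 and 0, and limma-trend on log2(TPM + 1) called 0 and 0. edgeR called 6 genes higher and 3 lower without mutant replicate 2, and 2 and 2 without wild-type replicate 2. Groups did not overlap for 4794 genes, 25.04% of those tested against 10% by chance. Of the 923 DESeq2 calls, 899 had non-overlapping groups. The 920 that edgeR tested had the same sign there, with an unadjusted p of at most 0.0269. Both tests used the same counts, so this overlap is not independent support. Lhx9, Dbx1, Myh3, Notch1, Mobp and Fndc3c1 were named under a rule that required non-overlapping groups. The 3 of 3 given for them below follows from that choice and is not added support. Igf2, H19, Cdkn1c and Ccnd1 were fixed beforehand. On simulated counts 22.96% of DESeq2 calls and 7.32% of edgeR calls were false. These shares need not hold for the data, since edgeR recovered 95.4% of simulated 4-fold changes but called 0 genes here. Leaving out mutant replicate 1 left 139 DESeq2 genes higher and 71 lower, and 196 of the 923 calls remained. Without mutant replicate 3 the counts were 185 and 119, with 265 of the calls remaining, and without wild-type replicate 2 they were 357 and 204, with 466 remaining. With sex as a covariate, an alternative chosen after seeing the data, DESeq2 called 255 and 123. With the file code as a term, also chosen after seeing the data, edgeR called 0 and 0, DESeq2 348 and 297, and camera 9 lists higher and 5 lower. In that edgeR fit the log2 fold changes were 1.36 for Igf2, 3.63 for H19, 4.66 for Myh3 and -2.04 for Mobp. Genes are said to have risen or fallen where they passed DESeq2, or edgeR adjusted over the list alone, and lists where they passed camera. None of these genes passed edgeR adjusted over all genes. The adjusted p there was 0.144 for Igf2, 0.149 for H19, 0.13 for Cdkn1c, 0.149 for Myh3, 0.125 for Notch1 and 0.154 for Mobp. Ranges over the alternatives leave out this main edgeR fit. For each list that passed camera, the adjusted p with an estimated correlation was the highest of all alternatives, and none passed with it.

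Markers of other cell types also moved with the genotype. Median log2 fold changes were -1.26 for oligodendrocyte, -0.70 for Purkinje cell, -0.27 for microglia, 0.26 for endothelial and 0.37 for pericyte and smooth muscle markers, and each of these lists passed camera, with adjusted p = 0.584 for each with an estimated correlation.

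Hox genes, which set position along the body axis and are textbook PRC2 targets, rose from near silence. Summed over the 39 Hox genes, expression was 2.30, 2.64 and 1.94 CPM in the wild-type libraries and 12.7, 8.18 and 15.2 CPM in the mutants. The number of Hox genes with at least 3 counts was 9, 8 and 6 in wild type and 25, 21 and 24 in the mutants. Of the 7 members with enough counts to test, 6 rose in edgeR adjusted over the list alone. Hoxb8 (chromosome 11, 96281905 to 96285315) had no counts in wild type and 1.55 ± 0.492 CPM in the mutants (n = 3), at least 13.7-fold higher against a floor of 3 counts per library. Hoxb3 rose by 4.40 on the log2 scale, to 1.16 ± 0.44 CPM, and Hoxa7 by 1.75. Hoxd8 had 2 counts over the wild-type libraries and 45 over the mutants, a ratio of 22.4 (95% counting interval 5.86 to 191). The list rose (median log2 fold change 3.12, also with Hoxb8 at its bound; camera adjusted p = 8.78e-08, and adjusted p = 0.584 with an estimated correlation). Without any 1 wild-type library 10 members passed, and 11 passed without mutant replicate 2. These counts exceed the 7 tested with all libraries because the filter then asked for enough counts in fewer libraries. They are therefore not a stronger result. Hoxb8, Hoxb3 and Hoxd8 cleared the filter only through the mutants. Hoxa7, at 0.378, 0.379 and 0.266 CPM in wild type, would not have cleared it on those libraries alone. The filter thus favoured genes high in the mutants, which bears on the count that rose, the median and the camera p. The median describes the tested members, not all 39 genes.

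Other developmental transcription factors rose with them. Of the 127 listed genes 58 had enough counts to test. Of these 13 rose and none fell in edgeR adjusted over the list alone, and DESeq2 called 11 higher. Shox2, at 0.0379 to 0.2265 CPM in wild type, cleared the filter only through the mutants, so the filter favoured such members here too. Lhx9, a LIM homeodomain factor (chromosome 1, 138825186 to 138848577), rose from 0.606 ± 0.136 to 7.99 ± 3.28 CPM (log2 fold change 3.71, SE 0.359, DESeq2 adjusted p = 1.26e-18, and up to 0.262 under other alternatives, higher in 3 of 3 mutants than in any wild-type tumour). Pax3, which marks dorsal neural tube and muscle precursors, rose by 2.13 on the log2 scale, from 2.50 ± 0.204 to 10.96 ± 3.82 CPM. Shox2 rose by 3.34, Six4 by 1.46 and Isl1, a motor neuron and heart factor, by 1.15. The list rose (median 0.25; camera adjusted p = 0.000561, and adjusted p = 0.584 with an estimated correlation). The count of members was 7 without wild-type replicate 2, 8 without wild-type replicate 3, 6 without mutant replicate 1 and 7 without mutant replicate 3. On the log CPM scale of camera the median was 0.26, and 0.165 without mutant replicate 1 and 0.394 without mutant replicate 2. Dbx1, a homeobox gene of neural progenitors outside the lists (chromosome 7, 49631499 to 49636849), rose from 0.405 ± 0.391 to 14.9 ± 7.27 CPM (log2 fold change 5.19, SE 0.713, DESeq2 adjusted p = 7.09e-06, and up to 0.423 under other alternatives, 3 of 3 mutants).

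Several imprinted genes rose in the mutants. Igf2, a fetal growth factor (chromosome 7, 142650766 to 142666816), was at 158 ± 34.2 CPM in wild type and 388 ± 149 CPM in the mutants (n = 3; log2 fold change 1.29, SE 0.278, DESeq2 adjusted p = 7.60e-05, and up to 0.462 under other alternatives, higher in 3 of 3). Its neighbour H19, a noncoding RNA (chromosome 7, 142575529 to 142578143), rose from 14.4 ± 13.0 to 144 ± 105 CPM (log2 fold change 3.32, DESeq2 adjusted p = 0.00935, with 0.00404 to 0.469 over the alternatives, 3 of 3). Cdkn1c, an inhibitor of cyclin-dependent kinases (chromosome 7, 143458339 to 143461050), rose from 12.02 ± 3.18 to 47.9 ± 22.3 CPM (log2 fold change 1.99, DESeq2 adjusted p = 9.20e-08, and up to 0.423 under other alternatives, 3 of 3). Dlk1, a Notch-like surface protein, rose by 4.24 on the log2 scale, Magel2 by 2.60 and Grb10, an adaptor that restrains insulin signalling, by 1.26. Adjusted over the list alone in edgeR, 6 of 27 imprinted genes rose and 2 fell, Dcn and Zrsr1. No fallen gene passed without wild-type replicate 1, wild-type replicate 2 or mutant replicate 1, and 1 passed without either of the other mutants. The list rose with the preset correlation (median 0.14; camera adjusted p = 0.0424, and adjusted p = 0.584 with an estimated correlation), but not without wild-type replicate 1 (adjusted p = 0.152) or mutant replicate 3 (0.0728). Its lowest adjusted p over the alternatives was 0.011. On the log CPM scale the median was 0.118, and 0.213, 0.219, 0.182 and 0.275 without wild-type replicates 2 and 3 and mutant replicates 1 and 2. Igf2, H19 and Cdkn1c were highest in mutant replicate 3, at 556, 264 and 73.2 CPM, as was the muscle gene Myh3 at 120.0 CPM. Within wild type these 4 genes were highest in wild-type replicate 3, at 196, 29.2, 15.5 and 5.78 CPM, and these 2 libraries share a file code. Fibroblast and meningeal markers had a median log2 fold change of -0.04, with a sign that turned without mutant replicate 2 (0.20) and with sex (0.08) or the file code (0.10) in the fit.

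Within the IGF axis 3 of 19 members rose and 3 fell in edgeR adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.406). Igf2bp3, a fetal RNA-binding protein, rose from 17.97 ± 8.68 to 54.7 ± 5.29 CPM, and Pappa, a protease that frees IGF from its binding proteins, rose by 1.06 on the log2 scale. Htra1 fell by 0.72, Irs2 by 0.36 and Igfbp2 by 0.31. The number that rose was 5 without wild-type replicate 3, and 1 fell without mutant replicate 1. Among 7 cyclin-dependent kinase inhibitors, Cdkn1c and Cdkn1a rose, the latter by 0.61, and only 1 member passed without mutant replicate 2 or mutant replicate 3. Cdkn2a, which encodes tumour suppressors that PRC2 silences in many cells, was at 0.366 ± 0.242 and 0.802 ± 0.201 CPM and did not pass (adjusted p = 0.27 in edgeR), with a log2 fold change of 1.12 that became 1.79 without wild-type replicate 1. This list did not pass camera (adjusted p = 0.0526) and passed fry (adjusted p = 0.0145) and camera without mutant replicate 3 (adjusted p = 0.0329), with library size only (0.0453), on log2(TPM + 1) (0.0255) and with the file code as a term (0.0385), with 0.0145 to 0.584 over the alternatives.

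Skeletal and cardiac muscle genes were higher in the mutants, and more members rose than in any other list. Of the 41 listed genes 32 had enough counts to test. Of these 24 rose and none fell in edgeR adjusted over the list alone, and DESeq2 called 19 higher. Chrng, at 0 to 0.19 CPM in wild type, and Tnnt2, at 0.0379 to 0.57, cleared the filter only through the mutants. The filter thus favoured members high in the mutants, so part of that count and of the list median follows from it. Myh3, the embryonic myosin heavy chain (chromosome 11, 67078300 to 67102291), rose from 2.43 ± 2.90 to 57.3 ± 55.3 CPM (log2 fold change 4.56, SE 1.04, DESeq2 adjusted p = 0.00636, and up to 0.469 under other alternatives, 3 of 3). Myh8, the perinatal myosin, rose by 4.18 on the log2 scale, the actin Acta1 by 3.51, the troponin Tnnt3 by 3.65, the giant sarcomere protein Ttn by 3.50 and the fetal acetylcholine receptor subunit Chrng by 3.99. Lmod3 and Hfe2, both muscle-expressed and outside the list, rose by 4.71 and 4.50. Myog, which drives muscle differentiation, went from 0.861 ± 1.30 to 12.9 ± 11.2 CPM and rose in edgeR adjusted over the list alone (adjusted p = 0.0161) but not in DESeq2 (adjusted p = 0.105), with 0.0276 to 0.481 over the alternatives and a log2 fold change of 3.90 that became 6.77 without wild-type replicate 3. Myod1, which commits cells to the muscle lineage, was at 61.7 ± 17.2 and 62.5 ± 12.7 CPM (log2 fold change 0.02, adjusted p = 0.975 in edgeR), and its sign reversed without wild-type replicate 1 or 2 or mutant replicate 2 or 3, to between -0.11 and -0.04. The list rose (median 2.85; camera adjusted p = 2.31e-12, and adjusted p = 0.584 with an estimated correlation). Adult fast myosins Myh1, Myh2 and Myh4 summed to 0.465 to 1.40 CPM in the mutants beside 26.1 to 166 CPM of Myh3 and Myh8. Pericyte and smooth muscle markers moved the same way (median 0.37; camera adjusted p = 0.0262, and adjusted p = 0.584 with an estimated correlation). They did not pass without wild-type replicate 1 (adjusted p = 0.0794), wild-type replicate 2 (0.0699) or mutant replicate 3 (0.067), and their lowest adjusted p over the alternatives was 0.0093. Their median on the log CPM scale was 0.372, and 0.247 without mutant replicate 3. Des, which rose by 2.22 on the log2 scale, is in both lists, so the pericyte and smooth muscle list is not separate from the muscle list.

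**Figure D2:**
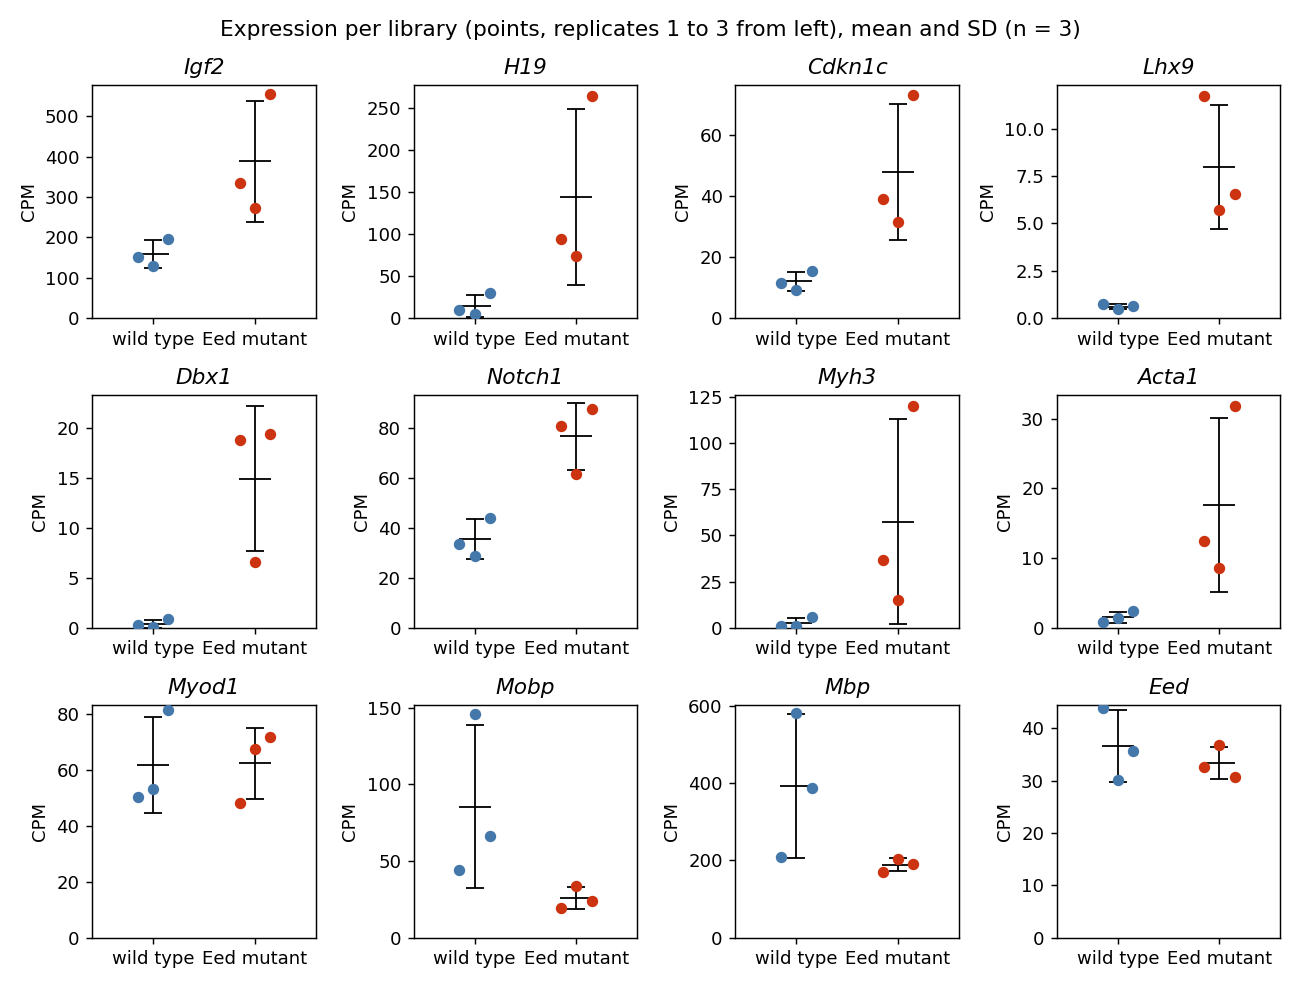
CPM per library (points, replicates 1 to 3 from left) of 12 genes in wild-type and Eed mutant tumours, with mean and SD (n = 3). The mutants lie above all wild-type libraries for Igf2, H19, Cdkn1c, Lhx9, Dbx1, Notch1, Myh3 and Acta1 and below them for Mobp and Mbp, while the groups overlap for Myod1 and Eed.

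Hedgehog pathway genes, which drive growth of granule neuron progenitors, were moderately higher. Of 21 tested members 6 rose and none fell in edgeR adjusted over the list alone. The pathway inhibitor Hhip rose from 60.8 ± 20.9 to 132 ± 29.9 CPM (chromosome 8, 79965851 to 80058006), Gli3 by 0.94 on the log2 scale, Gas1 by 0.79 and Cdon by 0.68. The target Ccnd1, a cyclin, went from 393 ± 126 to 644 ± 77.2 CPM. It rose in DESeq2 (adjusted p = 0.0367, and up to 0.54 under other alternatives, 3 of 3). In edgeR adjusted over all genes it did not pass (adjusted p = 0.205). Its log2 fold change of 0.71 became 0.47 without wild-type replicate 2. Gli1 was at 187 ± 31.8 and 238 ± 17.1 CPM (adjusted p = 0.235 in edgeR and 0.1475 in DESeq2). Ptch1 had a log2 fold change of 0.54 and Mycn of -0.20, and neither they nor Gli1 passed. Without wild-type replicate 2 the log2 fold changes of Gli1, Ptch1 and Mycn were 0.22, 0.29 and -0.32, that of Ptch1 was 0.83 without wild-type replicate 1, and that of Mycn was -0.10 without wild-type replicate 3. Ccnd2, another cyclin, was at 767 ± 89.3 and 617 ± 172 CPM (adjusted p = 0.417 in edgeR), with a log2 fold change of -0.32 that became -0.21, -0.57 and -0.20 without mutant replicates 1, 2 and 3. Gli2 had a log2 fold change of -0.01, with a sign that depended on the library left out. The list rose (median 0.24; camera adjusted p = 0.0234, and adjusted p = 0.584 with an estimated correlation) but not without wild-type replicate 2 (adjusted p = 0.114, with a lowest value of 0.00462 over the alternatives), and no member passed on its own without mutant replicate 1 or mutant replicate 3.

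Proliferation genes were slightly higher as a group. Of 40 tested members 38 had a positive log2 fold change, with a median of 0.24 (camera adjusted p = 8.26e-10, and adjusted p = 0.584 with an estimated correlation). The mitotic kinases Aurka and Plk1 rose by 0.36 and 0.39 in edgeR adjusted over the list alone, and DESeq2 called 4 members. On the log CPM scale the median was 0.24, and 0.157 without wild-type replicate 2. Mki67, the usual proliferation marker, was at 862 ± 108 and 1071 ± 169 CPM (adjusted p = 0.301 in edgeR). Without wild-type replicate 3, 22 members passed, while none passed without any other single library except mutant replicate 3, where 2 did. Granule neuron progenitor genes went both ways. Meis2 rose by 2.07, Barhl2, Zic4 and Rassf4 fell by 0.98, 0.46 and 0.41, and the progenitor factor Atoh1 was at 106 ± 27.3 and 160 ± 20.1 CPM without passing (DESeq2 adjusted p = 0.052, and up to 0.534 under other alternatives). That list did not pass (camera adjusted p = 0.938), with a median of -0.09 but a mean of 0.17 and an upward test. None of its members passed without mutant replicate 1 or mutant replicate 3. Without mutant replicate 2, 6 members fell.

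Notch pathway genes rose, including receptors, ligands and targets. Notch1 (chromosome 2, 26457903 to 26516663) rose from 35.6 ± 7.83 to 76.8 ± 13.4 CPM (log2 fold change 1.11, SE 0.186, DESeq2 adjusted p = 4.22e-06, and up to 0.434 under other alternatives, 3 of 3). The ligands Dll3, Dll4 and Jag1 rose by 1.38, 0.89 and 0.82, and the targets Heyl and Nrarp by 1.06 and 0.40. In edgeR adjusted over the list alone 7 of 17 members rose, and 2 fell, the ubiquitin ligase Dtx1 by 0.72 and the target Hey1 by 0.54. Without mutant replicate 1 only 2 rose, and without mutant replicate 3 only 3. A single member fell without wild-type replicate 1, wild-type replicate 3, mutant replicate 1 or mutant replicate 3. The list rose (median 0.46; camera adjusted p = 0.000724, and adjusted p = 0.584 with an estimated correlation). Endothelial cells also use this pathway, and their markers rose as a list (median 0.26; camera adjusted p = 0.0105, and adjusted p = 0.584 with an estimated correlation), though not without wild-type replicate 1 (adjusted p = 0.0833) or mutant replicate 1 (adjusted p = 0.0696) or with the file code as a term (adjusted p = 0.0608), with a lowest value of 0.00161 over the alternatives. Their median on the log CPM scale was 0.25, and 0.14, 0.395 and 0.162 without wild-type replicate 1 and mutant replicates 2 and 3. Kdr, Pecam1 and Flt1 rose by 0.56, 0.43 and 0.37 in edgeR adjusted over the list alone. None of the endothelial members passed without wild-type replicate 1, wild-type replicate 2, mutant replicate 2 or mutant replicate 3, 1 passed without mutant replicate 1, and 6 passed without wild-type replicate 3.

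Markers of oligodendrocytes, the myelin-forming cells, fell in the mutants. In edgeR adjusted over the list alone 13 of 19 fell and none rose. Mobp, a myelin protein (chromosome 9, 120149707 to 120181484), fell from 85.4 ± 53.3 to 25.8 ± 7.29 CPM (log2 fold change -1.73, SE 0.438, DESeq2 adjusted p = 0.0491, with 0.0272 to 0.481 over the alternatives, lower in 3 of 3). Cldn11 fell by 1.5 on the log2 scale, Mbp by 1.06 and Enpp6, a marker of newly forming oligodendrocytes, by 2.08. The list fell (median -1.26; camera adjusted p = 9.06e-07, and adjusted p = 0.584 with an estimated correlation). No member passed without mutant replicate 1. Wild-type replicate 2 stood apart, with the median marker 1.26 above its mean over the 6 libraries on the log2 scale, beside 0.13 and 0.24 in the other wild types. Without it the list median was -0.83, and the log2 fold changes of Mobp, Enpp6 and Cldn11 were -1.10, -1.37 and -0.99.

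Purkinje cell, granule neuron differentiation and interneuron markers were lower as lists too. All 15 Purkinje cell markers had negative log2 fold changes (median -0.70; camera adjusted p = 5.05e-05, and adjusted p = 0.584 with an estimated correlation). Calb1, Gad1 and Itpr1, a calcium buffer, the enzyme that makes GABA and a calcium channel, fell by 0.77, 0.70 and 0.61, and 5 members fell in edgeR adjusted over the list alone. The count was 13 without wild-type replicate 1 and 3 without mutant replicate 2, and no member passed without any of the other 4 libraries. Of 37 granule neuron differentiation genes 35 had negative log2 fold changes (median -0.39; camera adjusted p = 2.64e-05, and adjusted p = 0.584 with an estimated correlation). edgeR adjusted over the list alone called 0 of them, with 12 lower at an unadjusted p under 0.05, and DESeq2 called 5, among them Gabra6, a granule cell GABA receptor subunit, and Snap25, a synaptic protein, which fell by 1.00 and 0.81, with log2 fold changes of -0.57 and -0.52 without wild-type replicate 2. Neurod1 and Rbfox3, widely used neuronal markers, had log2 fold changes of -0.18 and -0.01 and did not pass, and their signs reversed without wild-type replicate 2 (0.05 and 0.06). Neurod1 was at -0.36 without wild-type replicate 1, and at -0.01 and -0.41 without mutant replicates 1 and 2. Rbfox3 also turned sign without wild-type replicate 3, mutant replicate 1 or mutant replicate 3, to at most 0.04. Without wild-type replicate 2 the medians were -0.45 for Purkinje cell and -0.16 for granule neuron differentiation genes. Relative to its mean over the libraries, the median Purkinje cell marker was at -0.108 in wild-type replicate 1, within the mutants (-0.491 to -0.099). Interneuron and unipolar brush cell markers fell as a list (median -0.42; camera adjusted p = 0.0262, and adjusted p = 0.69 with an estimated correlation), but not without wild-type replicate 2 (adjusted p = 0.409), wild-type replicate 3 (0.192) or mutant replicate 1 (0.318), and its lowest adjusted p over the alternatives was 9.66e-05. Its median on the log CPM scale was -0.411, and -0.148 without wild-type replicate 2.

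Astrocyte and Bergmann glia markers did not pass as a list (median -0.12; camera adjusted p = 0.0847), but passed without wild-type replicate 3 (adjusted p = 0.00555) or mutant replicate 3 (0.0205), with 0.00555 to 0.731 over the alternatives. Its median on the log CPM scale was -0.136, and 0.019 without mutant replicate 2, -0.29 without wild-type replicate 1 or 3 and -0.418 without mutant replicate 3. Of its 17 members 4 fell in edgeR adjusted over the list alone, Ntsr2 by 1.36, the gap junction gene Gjb6 by 0.94, Aldoc by 0.82 (log2 fold change -0.54 without wild-type replicate 2) and Acsbg1 by 0.52. That count was 1 without wild-type replicate 2 and 2 without wild-type replicate 1, mutant replicate 1 or mutant replicate 2. Microglia and macrophage markers fell as a list (median -0.27; camera adjusted p = 0.00134, and adjusted p = 0.584 with an estimated correlation), but not without wild-type replicate 1 (adjusted p = 0.0871) or with the file code as a term (adjusted p = 0.065), with a lowest value of 9.21e-07 over the alternatives. Their median on the log CPM scale was -0.245, and -0.1 without wild-type replicate 1 and -0.423 without wild-type replicate 3. edgeR adjusted over the list alone called 0 of its 20 members, with 3 lower at an unadjusted p under 0.05, and DESeq2 called 2, the receptors Csf1r and Mrc1, which fell by 0.54 and 0.65.

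**Figure D3:**
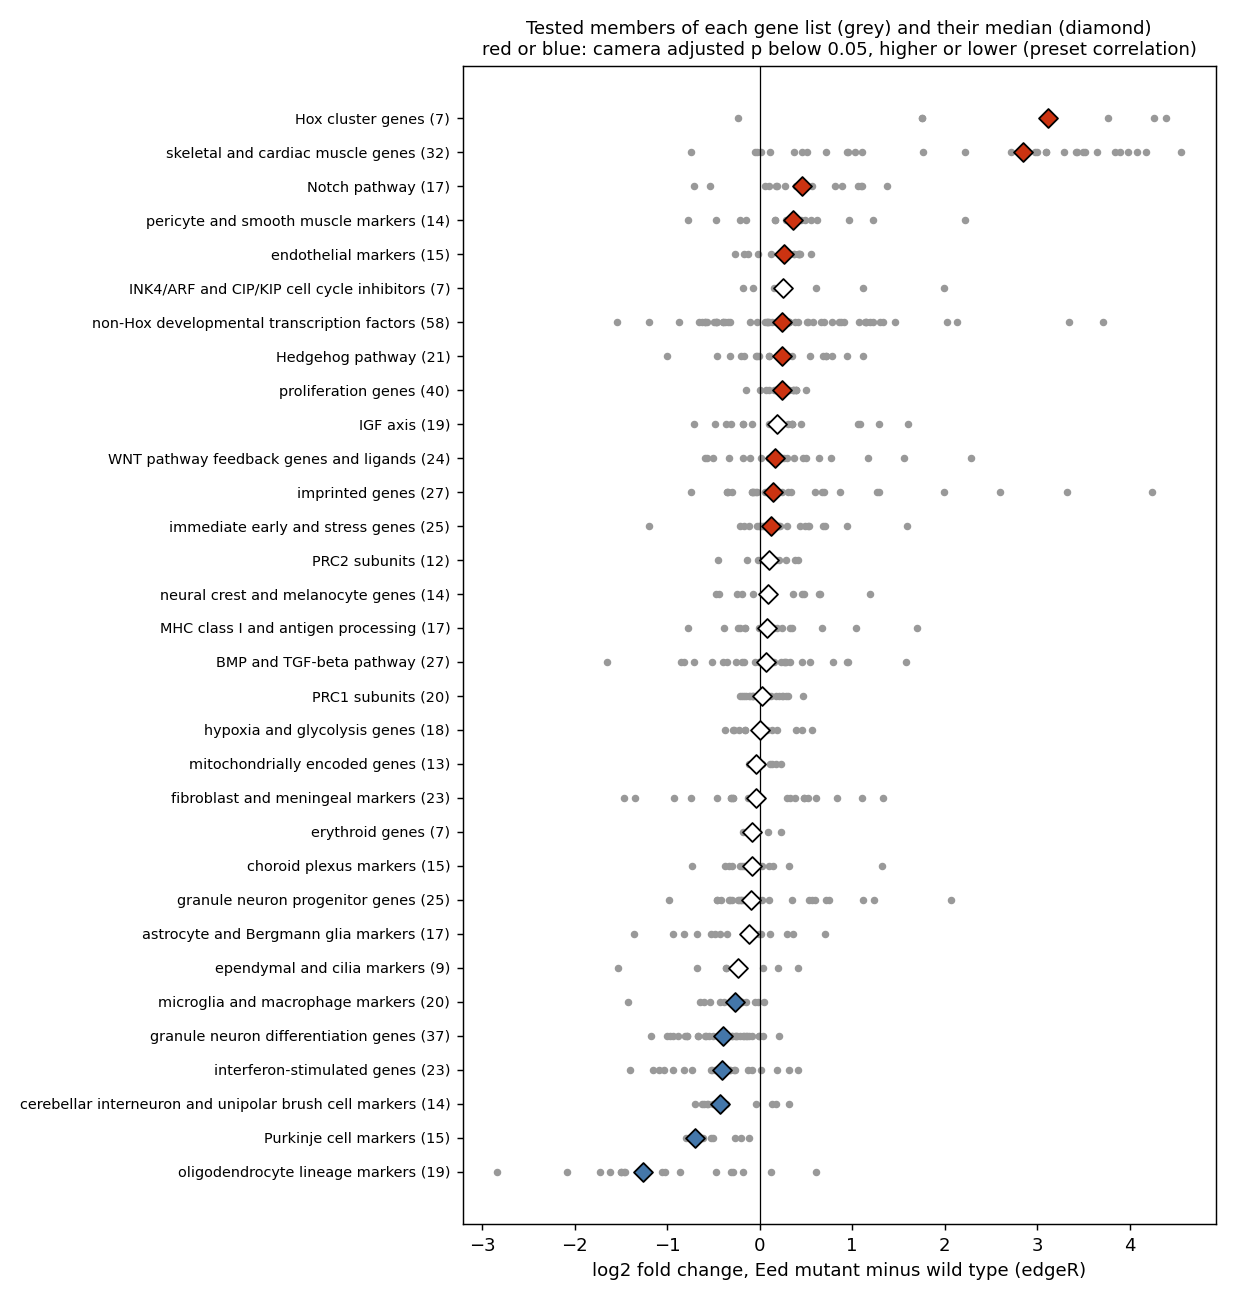
Log2 fold change (mutant minus wild type, edgeR) of the tested members of each gene list (grey points, number in parentheses) and the list median (diamond), with Hoxb8 drawn at its lower bound. Coloured diamonds mark camera adjusted p below 0.05 with the preset correlation, 11 lists higher (red) and 6 lower (blue), and 0 and 0 of these pass with an estimated correlation. Without wild-type replicate 1, 6 lists were higher.

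Most components of the Polycomb complexes did not pass any test. Ezh2, the main methyltransferase of PRC2, was at 170 ± 21.7 and 208 ± 10.3 CPM, and Suz12 at 167 ± 21.5 and 193 ± 10.3 CPM, and neither passed (adjusted p = 0.216 and 0.32 in edgeR). The log2 fold change of Suz12 was 0.21, and 0.11 without wild-type replicate 2. Ezh1, the alternative methyltransferase, fell by 0.46 on the log2 scale and Epop rose by 0.41 in edgeR adjusted over the list alone. Bmi1, a subunit of Polycomb repressive complex 1 (PRC1), rose by 0.47. Neither list passed camera (adjusted p = 0.119 for 12 PRC2 and 0.368 for 20 PRC1 subunits). No PRC2 or PRC1 subunit passed without wild-type replicate 1, mutant replicate 1 or mutant replicate 2. Without wild-type replicate 3, 4 PRC2 subunits rose, and 2 and 3 PRC1 subunits rose without wild-type replicate 2 and mutant replicate 3.

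Among all protein-coding genes the largest rises beyond those named included Fndc3c1 (chromosome X, 106420041 to 106485401), which went from 0.632 ± 0.366 to 20.6 ± 9.36 CPM (log2 fold change 5.02, SE 0.492, DESeq2 adjusted p = 6.78e-30, and up to 0.282 under other alternatives, 3 of 3). Among the largest falls, Krt12, a corneal keratin, fell by 2.81, Il12a, a cytokine subunit, by 2.33, Neu4, a sialidase, by 2.28, Fam107a by 1.80 and Bmp4 by 1.65. The log2 fold change of Il12a was -1.44 without wild-type replicate 1, and those of Fam107a and Bmp4 were -1.13 and -1.0 without wild-type replicate 2. Pcdha9 and Pcdha7 fell by 1.67 and 1.62, but these protocadherins share exons and their separate levels are uncertain.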

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

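Alternatives with robust or bias-adjusted edgeR fits, with sex as a covariate or the file code as a term, and those to the DESeq2 counts and to the counts within lists were chosen after seeing the data. Of the named genes' values under alternatives, 1996 kept direction and side of the threshold, 135 kept direction and passed it and 16 reversed. Since none passed in edgeR with all libraries (20 were fixed, 93 were DESeq2 calls), none could lose a pass. DESeq2 is among the alternatives, so for the 93 genes its pass was set by the choice and is not added support. Non-overlapping groups were a condition of that choice too. For the list medians, 402 kept both, 61 lost the pass, 10 gained it and 21 reversed. Of 288 counts of members within lists under alternatives, 140 stayed within 1.5 times, 32 were larger and 116 smaller. Where no cause is named, the cause was not tested.

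The edgeR count of 0 genes higher and 0 lower (3459 at an unadjusted p under 0.05) became 524 and 399 in DESeq2, 1 higher in limma-voom and 3 higher with no filter on low counts. Leaving out 1 library gave 0 to 6 higher and 0 to 3 lower. RLE factors, library size alone, the length offset, limma-trend on log2(TPM + 1), the stricter filter, protein-coding genes only, a minimum fold, an adjusted p below 0.01, robust and bias-adjusted fits, sex as a covariate and the file code gave 0 and 0. DESeq2 called 255 and 123 with sex as a covariate, 348 and 297 with the file code, and 139 to 670 higher and 71 to 587 lower with 1 library left out. Lists called higher, 11 with camera, were 0 with an estimated correlation, 2 in fry and 6 to 12 with 1 library left out. Lists called lower, 6 with camera, were 0 and 0 in the first 2 of these and 4 to 7 with 1 library left out. Sex as a covariate ended the calls of the imprinted, Hedgehog and WNT lists (adjusted p = 0.0535, 0.0641 and 0.0641), and the stricter filter those of the imprinted, WNT and interferon lists (0.182, 0.0883 and 0.0744). Over all alternatives the adjusted p ran up to 0.584 from 0.011 for imprinted, 0.00462 for Hedgehog and WNT and 0.00021 for interferon genes. Under the stricter filter too few Hox genes were left to test that list. With sex as a covariate no member of the Purkinje cell, interneuron, endothelial, proliferation, granule neuron progenitor or BMP lists passed adjusted over the list alone. With the file code the numbers that passed were 10 Hedgehog genes higher, 11 Notch genes higher and 1 lower, 7 progenitor genes higher, 13 Purkinje cell and 7 interneuron markers lower, 3 neural crest genes higher and 0 lower, 1 stress gene higher and 2 astrocyte markers lower. They were 0 in the PRC1, PRC2, WNT, BMP, proliferation, MHC and endothelial lists, and 0 lower in the IGF, imprinted and fibroblast lists.

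Same-numbered libraries had deviations correlated at 0.227, 0.062 and -0.135, and not every sample correlated best with its own number. The value of 0.227 was the highest of any pair. With 3 libraries per group these correlations cannot decide whether the replicate numbers pair the samples, and the main fits treated the samples as unpaired. With the replicate number as a block edgeR called 189 higher and 84 lower, DESeq2 519 and 538, and camera 12 and 6 lists, the cyclin-dependent kinase inhibitors among them (adjusted p = 0.0159, with 0.0145 to 0.584 over all alternatives).

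The Eed log2 fold change was 0.009 on log2(TPM + 1), 0.047 with the length offset, 0.02 with the file code and -0.253 to 0.019 with 1 library left out, with adjusted p from 0.406 to 0.975 over all alternatives. Rbfox3 was 0.009 with the length offset and Myod1 -0.013 with sex as a covariate and with the file code, and Gli2 0.046 with the file code. With 1 library left out the ranges were -0.103 to 0.057 for Rbfox3, -0.11 to 0.271 for Myod1, -0.122 to 0.056 for Gli2 and -0.409 to 0.053 for Neurod1. On log2(TPM + 1) the list medians were -0.054 for PRC1 and -0.017 for hypoxia genes. With sex as a covariate they were -0.008 for hypoxia genes, 0.082 for fibroblast, 0.121 for choroid plexus and -0.004 for erythroid markers. With the file code they were -0.035 for PRC1, -0.02 for hypoxia, 0.096 for fibroblast and -0.368 for erythroid genes. With 1 library left out they ran from -0.036 to 0.1 for PRC1, -0.055 to 0.039 for mitochondrial, -0.039 to 0.047 for hypoxia, -0.234 to 0.199 for fibroblast, -0.49 to 0.266 for choroid plexus, -0.418 to 0.019 for astrocyte and -0.155 to 0.706 for erythroid genes. Depth limits the Hox genes, as 32 of 39 had too few counts to test.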

Other observations

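The tests of muscle, oligodendrocyte, Purkinje cell and granule neuron differentiation genes, the fit with the file code, and the splits for DESeq2 calls and unadjusted p-values, were chosen only after the result was seen. The test of the share of Eed-202 and Eed-203 was not among those set beforehand either.

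Several gene groups outside the main account also moved. WNT feedback genes and ligands rose as a list (median log2 fold change 0.17; camera adjusted p = 0.0321, and adjusted p = 0.584 with an estimated correlation), with the feedback inhibitor Nkd1 higher by 0.77. This call ended without wild-type replicate 1 (adjusted p = 0.152), wild-type replicate 2 (0.0726) or mutant replicate 3 (0.067) and with the file code as a term (0.1195), with a lowest value of 0.00462 over the alternatives. The median on the log CPM scale was 0.255, and 0.146 without wild-type replicate 1 and 0.138 without mutant replicate 1. Nkd1 was the 1 member of 24 that passed in edgeR adjusted over the list alone, none passed without wild-type replicate 1 or 2 or mutant replicate 1 or 2, and 3 passed without wild-type replicate 3. Immediate early and stress genes rose as a list (median 0.12; camera adjusted p = 0.0234, and adjusted p = 0.584 with an estimated correlation), but not without wild-type replicate 1 (adjusted p = 0.152) or with the file code as a term (0.1195), with a lowest value of 0.00694 over the alternatives, and their log CPM median went from 0.124 to 0.194 without mutant replicate 2. Of 25 members, the growth arrest gene Gadd45g rose by 1.59 and Btg2 by 0.70 in edgeR adjusted over the list alone, and 2 members passed without mutant replicate 2 but only 1 without each other library. Hspa1b fell by 1.19 in DESeq2 (log2 fold change -0.73 without wild-type replicate 3), but shared reads leave its level uncertain. Interferon-stimulated genes fell as a list (median -0.41; camera adjusted p = 0.00861, and adjusted p = 0.584 with an estimated correlation), but not without wild-type replicate 1 (adjusted p = 0.0871) or wild-type replicate 2 (0.0775), with a lowest value of 0.00021 over the alternatives. Their log CPM median was -0.363, and -0.207 without wild-type replicate 2 and -0.674 without wild-type replicate 3. edgeR adjusted over the list alone and DESeq2 each called 0 of its 23 members, with 2 lower at an unadjusted p under 0.05.

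Members of several further lists passed edgeR adjusted over the list alone. Of 14 neural crest and melanocyte genes, 6 rose and 1 fell in edgeR adjusted over the list alone (camera adjusted p = 0.123, and 0.0179 without mutant replicate 2, with 0.584 the highest over the alternatives), with Sox8 higher by 0.65, the neurotrophin receptor Ngfr by 0.65 and Kit lower by 0.44 (log2 fold change -0.44). The number that rose was 0 without wild-type replicate 2, mutant replicate 1 or mutant replicate 3, 1 without wild-type replicate 1 and 4 without wild-type replicate 3. No member fell without wild-type replicate 1 or 2 or mutant replicate 1 or 3, and 2 fell without wild-type replicate 3. In the MHC class I list (camera adjusted p = 0.393) H2-Q7 and H2-Q4 rose by 1.71 and 1.04, neither passed without mutant replicate 1 or 2, and reads shared between these paralogs leave their levels uncertain. The BMP and TGF-beta list of 27 tested genes had a camera adjusted p of 0.368. Of 23 fibroblast and meningeal markers 3 rose and 4 fell (camera adjusted p = 0.772), with no member passing without mutant replicate 1. Without wild-type replicates 1, 2 and 3 the numbers were 4 and 6, 1 and 1, and 1 and 1, and without mutant replicate 3 they were 1 and 4. Of 15 choroid plexus markers the tight junction gene Cldn2 rose by 1.33, and 1 member passed with each library left out (camera adjusted p = 0.772 for the list). In the pericyte and smooth muscle list, which passed camera, 3 of 14 rose, Des, Acta2 and Rgs5, and 5 rose without mutant replicate 2. Of 14 interneuron and unipolar brush cell markers, a list that also passed camera, 2 fell, Gad1 and Kit, 8 fell without wild-type replicate 1, 1 without wild-type replicate 3, and none without the remaining libraries. Gad1 is also in the Purkinje cell list, and Kit is also in the neural crest list. Camera adjusted p was 0.295 for ependymal and cilia markers, 0.734 for erythroid genes (0.00801 without wild-type replicate 2, with 0.998 the highest over the alternatives), 0.772 for mitochondrially encoded genes, 0.739 for hypoxia and glycolysis genes and 0.552 for sex-linked genes. For mitochondrially encoded genes the median was -0.04 and the mean 0.02, for fibroblast markers -0.04 and 0.02, for hypoxia genes the median was 0.02 with a downward test, and for erythroid genes the edgeR median was -0.08 with an upward test. edgeR adjusted over the list alone called 0 members of the ependymal, erythroid, mitochondrial, hypoxia and sex-linked lists, with 3 hypoxia genes, 1 mitochondrial gene and 1 ependymal gene at an unadjusted p under 0.05, and DESeq2 called only Bnip3, a hypoxia gene that fell by 0.38. Only 4 lymphocyte and neutrophil markers had enough counts, so that list was not tested.

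Muscle genes were higher in the mutants, most of all in mutant replicate 3. Adult skeletal muscle carried into the tumour pieces would bring adult fast myosins, but their ratio to embryonic and perinatal myosins was at most 0.0178 in the mutant libraries, which argues against it. A single library did not carry the pattern either, since 24 of 32 tested members were higher in both other mutants than in every wild-type tumour. Some of these, such as Chrng, cleared the filter only through the mutants, so part of this count follows from the filter. A candidate explanation that stays open is an embryonic-type muscle program in cells of the mutant tumours, where Myod1 was at 62.5 CPM beside 61.7 CPM in wild type. Immature or regenerating muscle in the pieces was not tested and stays open too.

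Oligodendrocyte markers were lower in the mutants. Less tissue of every other cell type would lower all markers alike. The endothelial median lay 1.52 above the oligodendrocyte median on the log2 scale (95% bootstrap interval over members 0.717 to 1.87). That interval does not cover the spread between tumours. With 1 library left out the log CPM medians ran from 0.14 to 0.395 for endothelial and from -1.336 to -0.822 for oligodendrocyte markers. This argues against a like loss of endothelial and oligodendrocyte cells, and other cell types were not compared. Wild-type replicate 2 was not the whole source for oligodendrocyte markers, because without it their median was -0.83. For Purkinje cell markers the median without it was -0.45. Relative to the mean over libraries, wild-type replicate 1 (-0.108) then lay among the mutants (-0.491 to -0.099), and only wild-type replicate 3 (0.303) lay above them. For granule neuron differentiation genes the median moved from -0.39 to -0.16 without wild-type replicate 2. Wild-type replicates 1 and 3 (-0.032 and 0.031) lay near mutant replicate 2 (0.023), so much of this signal may come from wild-type replicate 2. Less normal cerebellar tissue in the mutant pieces and an effect of the genotype both stay open.

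Igf2 was higher in the mutants. More fibroblast or meningeal cells would raise their markers, but the median over 23 such markers was -0.043 (95% bootstrap interval -0.292 to 0.387), below 0.646, the level set as 50% of the Igf2 log2 fold change. That interval is over markers, not tumours. Within each group the marker median per library followed the order of Igf2. Relative to the mean over libraries it was -0.017, -0.287 and 0.336 in mutant replicates 1 to 3, and 0.008, -0.173 and 0.021 in wild type. Mutant replicates 1 and 2 lay below wild-type replicates 1 and 3 for the markers but above every wild type for Igf2. This argues against those cells as the whole source, while a part from them stays open. A direct effect of the Eed genotype also stays open and was not tested. Cells that express the muscle genes stay open as a source too, since Igf2 and Myh3 were both highest in mutant replicate 3 (556 and 120.0 CPM) and, within wild type, in wild-type replicate 3 (196 and 5.78 CPM), 2 libraries that share a file code. Near Eed on chromosome 7, within 20 Mb, 17 of 323 genes were DESeq2 calls (5.26%) against 904 of 17322 elsewhere (5.22%; one-sided Fisher's exact p = 0.522, odds ratio 1.01, 95% interval 0.578 to 1.65), so no excess that a linked strain difference would bring was seen.

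The 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05. edgeR called 0 genes in the real split (3459 at an unadjusted p under 0.05; 923 in DESeq2) and at most 6 in another. Every split reaches a count of 0, so that all 10 did so says nothing about chance. DESeq2 called 524 higher and 399 lower in the real split, and at most 47 in either direction in another, so 1 of 10 reached each count. These counts were 139 and 71 without mutant replicate 1, 185 and 119 without mutant replicate 3, and 357 and 204 without wild-type replicate 2. edgeR called 6 and 3 genes without mutant replicate 2, and 2 and 2 without wild-type replicate 2. For genes at an unadjusted p under 0.05 the real value was 3459 and the highest other 1315, again 1 of 10. Camera called 11 lists higher in the real split and at most 11 in another, with 2 of 10 as many (6 without wild-type replicate 1), and 6 lower against at most 11, with 6 of 10 as many.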
